A study of Homo sapiens with 20 samples.

How the data were processed

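Gene expression was measured on 20 Affymetrix arrays from 5 human T cell acute lymphoblastic leukaemia (T-ALL) lines, which were CEM, DND41, HPB-ALL, KOPT-K and T-ALL1. Each line was given a control peptide or the NEMO-binding domain (NBD) peptide for 16 h, with 2 arrays per line and peptide, which makes 10 groups. Per the labels' protocols, RNA was isolated on silica columns, and 20 ng of total RNA was amplified in a pair of cycles and labelled with biotin. The labels give the peptide dose in conflicting units, 100 µM in the sample descriptions and the series design and 100 mM in the source names and the treatment protocol, so no statement here rests on the dose. The labels do not say whether the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical, except in the fit with lines as replicates.

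The deposited table holds 1 linear intensity per probe set and array for 54675 probe sets, and the submitters' processing notes name RMA (robust multi-array average), with no version. The values were on a linear scale and were taken to log2 here with no pseudocount. The columns fall into 2 kinds. Those of T-ALL1 and KOPT-K hold up to 7 decimals with mean intensities of 386.9 to 396.1, and those of CEM, DND41 and HPB-ALL hold 2 decimals with mean intensities of 341 to 347.7. The authors therefore appear to have normalized the arrays in 2 runs. Both peptides of a line have values of the same kind, so each NBD effect was computed within 1 such set of columns, while levels set side by side across the sets seem to come from separate normalizations. These sets are called processing runs here, although no source used here states them. The median intensity per array was 30.33 to 34.09. An array has no read depth, so the number of arrays limits the precision.

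Probe sets were named through the platform's probe table. Of the 54675, 41097 had 1 gene symbol, 1801 had several and 11777 had none, 62 control probe sets among the last. For 41043 of those with 1 gene, the symbol was found in a gene table of assembly GRCh38.p14, which was used for names only. Probe sets with several genes or none were left out of the gene-level tests. Each of the 19775 genes was represented by its probe set with the highest mean over the 20 arrays. A gene was kept if it reached the median of all deposited values, an intensity of 31.96 or a log2 value of 5, on at least 2 arrays, which left 13787 genes. Some genes of the lists are not reported here.

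Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on log2 values, with 1 mean per group and a spread shared over the 10 groups, and with Benjamini-Hochberg adjustment at 0.05. That fit has 10 residual degrees of freedom and 3.42 prior degrees of freedom. Every difference is NBD minus control. The tests were the effect in each line, the mean of the 5 effects with equal weight (the average NBD effect) and a moderated F-test of whether the effect differs between lines. A further fit took the means of the 10 groups with the line as a block, so that the 5 lines served as replicates (4 residual and 4.18 prior degrees of freedom). The average effect describes these 5 lines, and only the fit with lines as replicates uses the spread between lines.

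A set of 20 gene lists was fixed before the data were examined: NF-kB targets, IKK and NF-kB pathway components, Notch pathway targets, apoptosis regulators, p53 targets, mitosis, DNA replication, MYC and ribosome biogenesis, the integrated stress response, endoplasmic reticulum chaperones, cytosolic heat shock, immediate-early genes, cholesterol synthesis, interferon-stimulated genes, NRF2 targets with metallothioneins, hypoxia and glycolysis, T lineage identity, and markers of B cells, of myeloid cells and of fibroblasts and epithelium. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. A list's test in each line formed a second family of 100 tests. The difference of a list's mean shift between lines was tested on the mean of its genes per array.

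The genes named were set by a rule written before the data were examined. It takes the 12 largest average changes in each direction among genes past the threshold with the same sign in all 5 lines, and the 3 largest changes in each direction in each line. It adds the 5 genes with the lowest p for a difference between lines, and up to 4 members of each list past the threshold, or the 2 largest where none passed. NFKBIA, TNFAIP3, CYLD, HES1, IKBKB, CHUK and IKBKG were always named.

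The procedures were tested on simulated data for 13787 genes, of which 200 were changed. The average over 5 lines recovered 97% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1, with 10 unchanged genes called. The fit with lines as replicates recovered 95% and 100% with 11 called. In both cases the simulated change was the same in every line. These shares therefore do not hold for effects that vary between lines, for which the fit with lines as replicates was not tested. The test in a single line recovered 55% and 89% with 10 called, and the test of a difference between lines recovered 17% and 61% of changes confined to CEM with 4 called. The alternatives tried were leaving out each array or each line, other filters, other ways of choosing probe sets, median centring, quantile normalization, a trended robust prior, array weights, an additive model, each line's arrays alone and the replicate number as a block. Each processing run alone and the actin 3' to 5' difference as a covariate were added after seeing the data, as was an estimated correlation for the lists in subsets of lines. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.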

Results

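The arrays measured transcript levels in 5 T-ALL lines 16 h after a control peptide or the NBD peptide, which blocks canonical NF-kB activity by parting the regulatory subunit of the IkB kinase from its catalytic subunits. Each line had 2 arrays per peptide, 20 in all, and 13787 genes were tested. Arrays of 1 group correlated at r = 0.992 to 0.998 across genes and arrays of different lines at 0.86 to 0.923. All 20 arrays correlated best with an array of their own line, and 18 with the other array of their own group. The log2 difference between the 3' and 5' probe sets of actin, a sign of RNA integrity, was 3.16 and 2.05 on the T-ALL1 control arrays. It was 1.03 ± 0.05 (SD, n = 2) with NBD in that line, and the other group means lay between 0.85 and 1.76. Over all lines it differed by -0.312 between the peptides, which an exact two-sided permutation test within lines did not separate from chance (p = 0.174, 7776 assignments). That p does not show balance between the peptides. The difference came from T-ALL1, where 2 arrays per peptide leave too few assignments for a low p. The GAPDH difference was -0.045 (exact permutation p = 0.764). Without T-ALL1 the actin difference was 0.004, a mean over lines that went in opposite directions. The means with control and NBD were 1.45 and 1.76 in CEM and 1.42 and 1.27 in DND41. They were 0.94 and 0.85 in KOPT-K and 1.37 and 1.3 in HPB-ALL. In CEM and DND41, as in T-ALL1, the arrays of the peptides did not overlap, so RNA integrity may differ with the peptide there too.

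**Figure D1:**
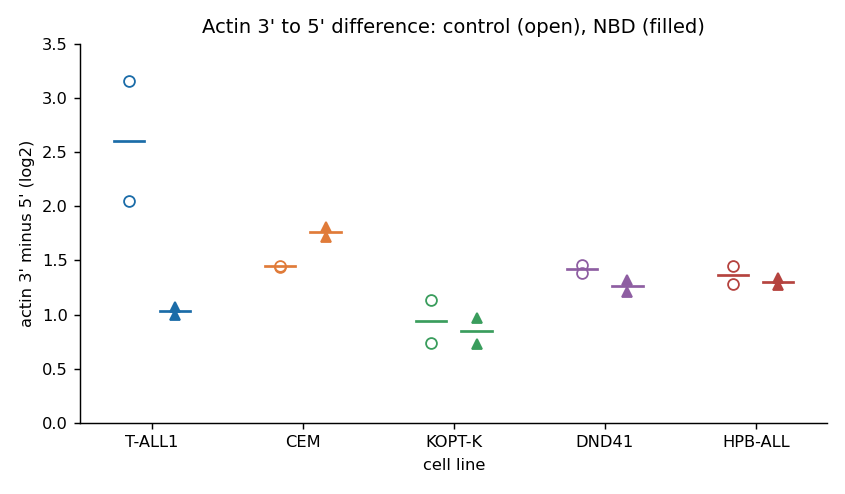
Log2 difference between the 3' and 5' actin probe sets on each array, by line, with control arrays as open circles, NBD arrays as filled triangles and the group mean as a line. The T-ALL1 control arrays, at 3.16 and 2.05, lie above all others.

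The first question was which transcripts changed with the NBD peptide on average over the 5 lines. JUN, a subunit of the AP-1 transcription factor, rose most, by 1.33 ± 0.04 on the log2 scale (SE, 2 arrays per group, 2.52-fold; limma adjusted p = 4.37e-10), and was called higher in each of the 5 lines. Metallothionein genes, whose products bind zinc and copper, followed. MT1X rose by 1.12 ± 0.06 and MT2A by 0.94 ± 0.04, and MT1H, MT1G, MT1F, MT1HL1 and MT1E by 0.81 to 1.00. The probe sets of these metallothioneins are of the kind that can share probes with near-identical genes, so which members rose is uncertain. ID3 and ID1, inhibitors of basic helix-loop-helix transcription factors, fell by 1.47 ± 0.05 and 1.45 ± 0.07 (limma adjusted p = 8.41e-10 and 2.42e-08), and ID3 was -0.06 in HPB-ALL. HES1, a transcriptional repressor induced by Notch, fell by 1.09 ± 0.10 (limma adjusted p = 2.95e-05) and was lower in all 5 lines. Of the other probe sets of HES1, 1 gave -0.962 (limma adjusted p = 1.81e-06). Another, with a mean log2 level of 3.49 below the filter value of 5, gave -0.098 (0.441). The other probe sets of JUN, MT1X, MT1F and MT1E passed, and that of MT1G, at a level of 3.76, gave 0.068 and did not.

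Among the other genes named by rule, ATF3, a stress-induced transcription factor, rose by 0.85 ± 0.06, and DUSP16 and DUSP10, phosphatases of MAP kinases, by 0.62 ± 0.06 and 0.55 ± 0.07. RAB30, a small GTPase, rose by 0.61 ± 0.12. CD300A, an inhibitory receptor, fell by 1.02 ± 0.06, LZTFL1 by 0.93 ± 0.07, SASH3, a lymphocyte adaptor, by 0.73 ± 0.06, and NOTCH3, a Notch receptor, by 0.71 ± 0.07. TMC6, DTX1, MOSMO, WDR4 and LCT-AS1 fell by 0.53 to 0.59. Of the genes named in advance, NFKBIA and TNFAIP3, which encode inhibitors of NF-kB signalling, both rose by 0.33 (SE 0.04 and 0.03; limma adjusted p = 0.000107 and 3.96e-05). CYLD, a deubiquitinase that restrains NF-kB, was 0.07 ± 0.05 (limma adjusted p = 0.407), IKBKB -0.11 ± 0.05 (0.236), CHUK 0.02 ± 0.05 (0.857) and IKBKG 0.03 ± 0.03 (0.651), and none of these kinase subunit genes passed. Other probe sets of these genes passed in part. In limma, 1 passed for each of ATF3, DUSP16, DUSP10, RAB30, CD300A, LZTFL1, TMC6 and TNFAIP3. Those that missed the threshold gave -0.046 for ATF3, 0.113 and 0.017 for DUSP16 and 0.179, 0.146 and 0.06 for RAB30. They gave -0.07 for CD300A and -0.109 and -0.108 for LZTFL1. No other probe set passed for NFKBIA (0.012, limma adjusted p = 0.899), NOTCH3 (0.032) or WDR4 (0.006 and -0.106). That of NFKBIA had a mean log2 level of 3.93, below the filter value, and NFKBIA was called higher in 3 lines. Those of NOTCH3 (5.53) and WDR4 (5.74 and 5.29) lay above the filter value. Over the average and single-line changes called for named genes, other probe sets were called the same way in 44 comparisons and not in 56. In 30 of the 56, and 2 of the 44, the probe set had a mean level below the filter value.

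**Figure D2:**
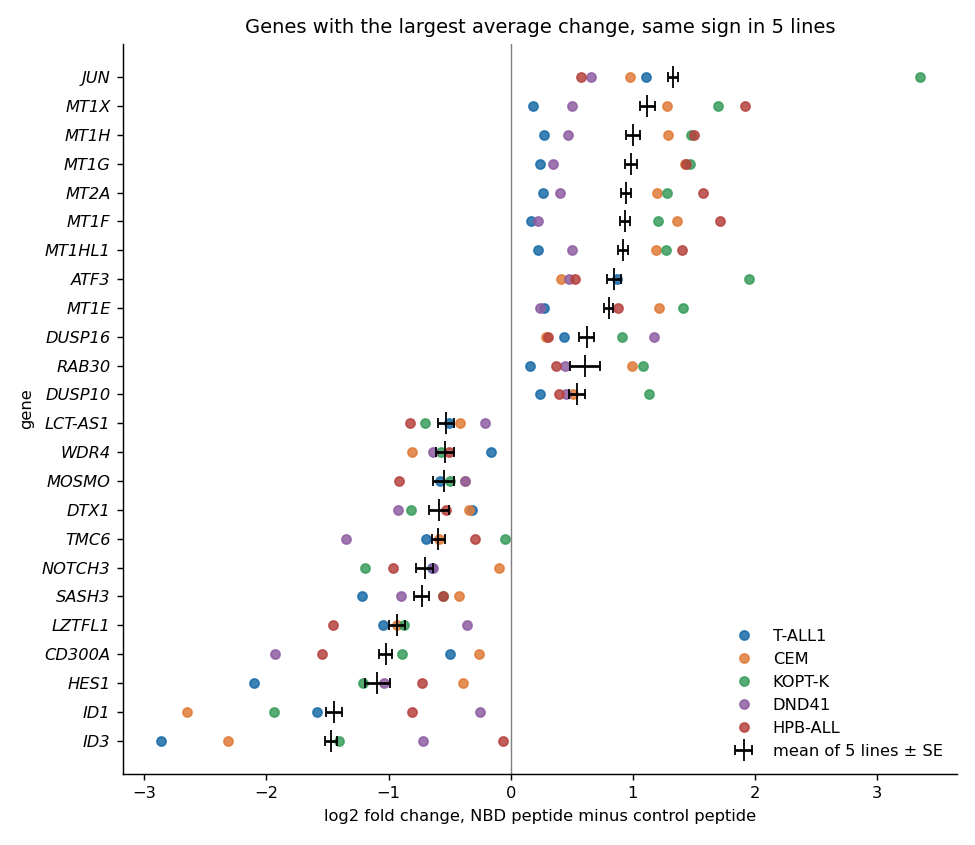
Log2 fold change, NBD minus control, of the 12 genes with the largest average change in each direction, with 1 point per line and a cross for the mean of 5 lines with its SE. JUN stands highest at 1.33 with KOPT-K at 3.35, and ID3 lowest at -1.47 with HPB-ALL at -0.06.

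In all, 309 genes rose and 847 fell with limma, 12 and 9 of them past 1.5-fold, and 755 of the 1156 had the same sign in all 5 lines (181 higher and 574 lower). Over all genes, 13.1% had the same sign in 5 lines, where independent signs give 6.25%. The 1156 were picked by the mean of the same 5 effects, which favours equal signs, so their share cannot be set against these. With the lines as replicates limma called 0 genes, at a lowest adjusted p of 0.126. In that fit 1639 genes (482 higher, 1157 lower) had an unadjusted p under 0.05 against 689 expected by chance, 928 of the 1156 among them, and a trended robust prior called 69. Both fits use the same mean effects, so the 928 are no independent support for a shared effect. The counts depended on single arrays: leaving out T-ALL1 control 2 gave 702 higher and 1612 lower, leaving out HPB-ALL NBD 1 gave 193 and 561, and leaving out CEM NBD 1, DND41 control 2, KOPT-K NBD 2 or HPB-ALL NBD 2 gave 198, 200, 205 and 205 higher. T-ALL1 and KOPT-K, which by the form of their values seem to come from 1 processing run, gave 16 higher and 8 lower when fitted alone, and CEM, DND41 and HPB-ALL gave 208 and 769. The first of these fits had fewer arrays and held the T-ALL1 control pair, whose replicate spread was the largest (SD 0.318). The contrast therefore does not measure a difference between runs.

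**Figure D3:**
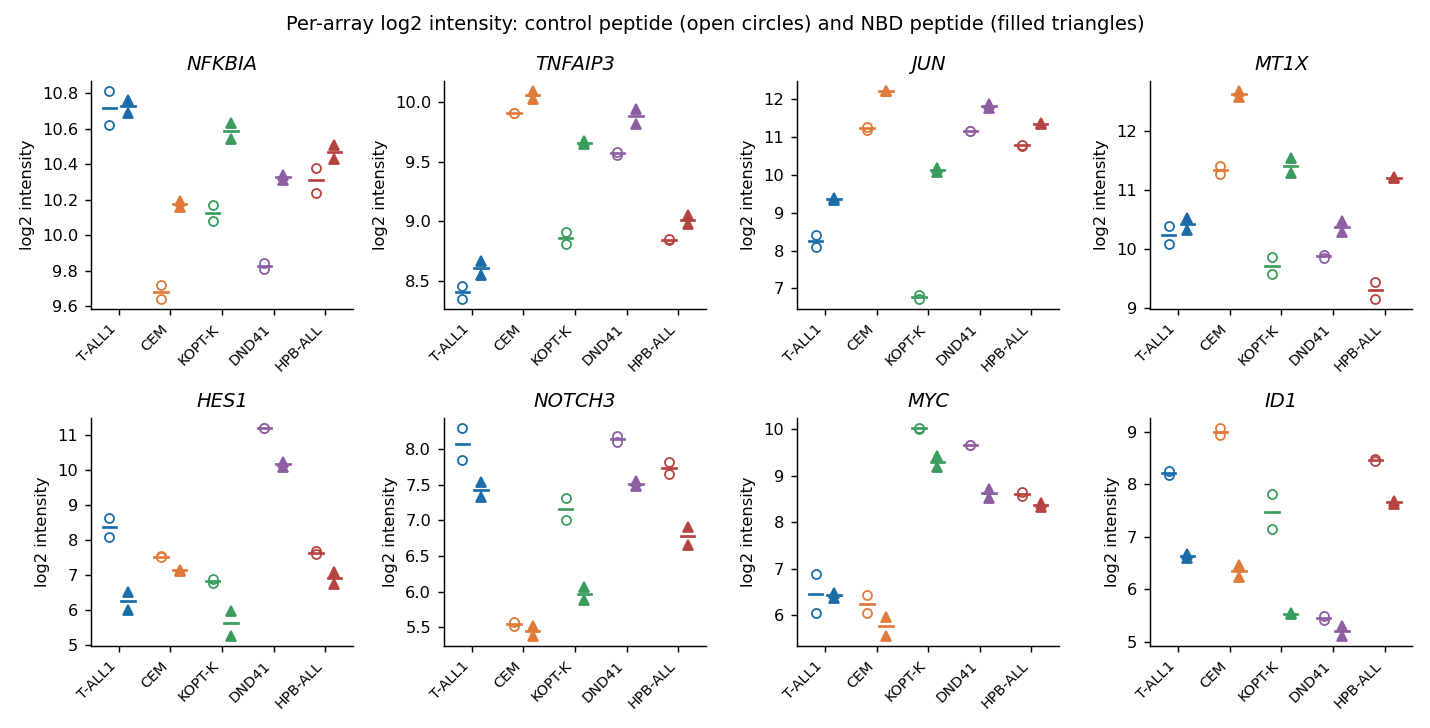
Log2 intensity of 8 genes on each array, with control arrays as open circles, NBD arrays as filled triangles and group means as lines; each panel has its own axis, and levels of T-ALL1 and KOPT-K seem, from the form of their values, to have been normalized apart from those of the other lines. JUN is higher and HES1 lower with NBD in every line.

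The gene lists asked which pathways moved together. NF-kB targets rose as a group, with 8 of 36 measured members higher and 0 lower (10 and 1 adjusted over the list alone; mean 0.083, camera adjusted p = 5.82e-05). RELB, an NF-kB subunit, rose by 0.35 ± 0.08 and CD83, an activation marker, by 0.33 ± 0.05, beside NFKBIA and TNFAIP3. Of 25 pathway components measured, 0 rose and 1 fell, also adjusted over the list alone, and that was COMMD1 at -0.16 ± 0.04 (mean -0.025, camera adjusted p = 0.995). The COMMD1 call was lost without HPB-ALL NBD 1 (-0.152, limma adjusted p = 0.0542) or KOPT-K NBD 2 (-0.142, 0.0533). Notch pathway targets fell, 9 of 21 with 0 higher (11 and 0 adjusted over the list alone; mean -0.25, camera adjusted p = 1.34e-06). These included HES1, NOTCH3, DTX1 at -0.59 ± 0.08 and CR2, a complement receptor, at -0.56 ± 0.07. CR2 did not have the same sign in all 5 lines, and its effect differed between them (limma moderated F-test, adjusted p = 0.0045). Another probe set of CR2, at a mean log2 level of 2.73, gave -0.02. In none of the 5 lines did the NF-kB list pass with an estimated correlation (camera adjusted p = 0.1 to 0.842).

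Cholesterol synthesis genes gave the lowest p of the 20 lists, with 16 of 21 higher and 0 lower (17 and 1 adjusted over the list alone; mean 0.227, camera adjusted p = 5.74e-20). MSMO1, HMGCS1 and DHCR7, enzymes of the pathway, rose by 0.48 ± 0.05, 0.45 ± 0.04 and 0.45 ± 0.07, and SCD, a fatty acid desaturase, by 0.34 ± 0.03. Of the other probe sets of SCD, 1 passed and 2 gave 0.377 and 0.387 (limma adjusted p = 0.0603 and 0.0806). Of the NRF2 and metallothionein list 8 of 21 rose and 0 fell (10 and 4 adjusted over the list alone; mean 0.303, camera adjusted p = 9.8e-10), where 6 of the 8 were metallothioneins. The others were SLC30A1, a zinc exporter, and TKT, an enzyme of the pentose phosphate pathway. The metallothioneins of the list rose by 0.81 to 1.12, so its mean rests largely on them. Their probe sets can share probes and may repeat 1 signal. The NRF2 targets were not tested as a list without them, so no rise of NRF2 targets as a group is shown. Of the immediate-early genes 9 of 27 rose and 1 fell (16 and 2 adjusted over the list alone; mean 0.202, camera adjusted p = 2.12e-10), with JUN, ATF3, FOS at 0.59 ± 0.11 and JUND at 0.47 ± 0.03. Of the 3 other probe sets of JUND, 2 passed and 1 gave 0.031. The mean of the immediate-early list was 0.098 without KOPT-K (camera adjusted p = 0.000107; adjusted p = 0.0867 with an estimated correlation), 0.336 in T-ALL1 and KOPT-K alone and 0.113 in the other 3 lines. In DND41 it was -0.126, with 2 members higher and 3 lower and camera pointing up (adjusted p = 0.887).

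T lineage identity genes fell, 11 of 32 lower and 1 higher (13 and 1 adjusted over the list alone; mean -0.132, camera adjusted p = 6.01e-07). CD3D, a chain of the T cell receptor complex, fell by 0.45 ± 0.03, and CD1B, CD7 and CD1E by 0.31 ± 0.06, 0.29 ± 0.04 and 0.27 ± 0.06. Other probe sets gave -0.19 for CD7 (limma adjusted p = 0.0742) and -0.12 for CD1E (0.565). MYC and ribosome biogenesis genes fell, 6 of 27 lower and 0 higher (13 and 0 adjusted over the list alone; mean -0.108, camera adjusted p = 1.43e-05). MYC fell by 0.50 ± 0.09, SRM, which makes spermidine, by 0.32 ± 0.04, RRS1 by 0.23 ± 0.03 and NOP16 by 0.16 ± 0.04. Of the other probe sets of NOP16, 1 gave -0.344 and 2 gave 0.081 and 0.07, which did not pass. The NOP16 call was lost without any 1 of 11 single arrays, with changes of -0.166 to -0.132 and limma adjusted p up to 0.072. In T-ALL1 and KOPT-K alone the mean of this list was -0.068 (camera adjusted p = 0.069). Without DND41 it was -0.067 (camera adjusted p = 0.0233 with the preset correlation, 0.16 with an estimated one).

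Another 3 lists passed with the preset correlation only. Of the integrated stress response genes 7 of 30 rose and 0 fell (8 and 0 adjusted over the list alone; mean 0.09, camera adjusted p = 3.57e-05; adjusted p = 0.179 with an estimated correlation), with ATF3, PPP1R15A at 0.41 ± 0.06, SLC3A2 at 0.23 ± 0.06 and SESN2 at 0.22 ± 0.06. Of the p53 targets 4 of 22 rose and 0 fell (6 and 0 adjusted over the list alone; mean 0.041, median -0.005; camera adjusted p = 0.0319; adjusted p = 0.103 with an estimated correlation), namely GADD45A, CDKN1A, SESN2 and PLK2 at 0.26, 0.24, 0.22 and 0.20. Of the DNA replication genes 4 of 34 rose and 1 fell (7 and 2 adjusted over the list alone; mean 0.027, camera adjusted p = 0.0317; adjusted p = 0.172 with an estimated correlation), with CDT1, CDC6 and DTL at 0.32, 0.18 and 0.13 and POLA2 at -0.16. Several of these calls were lost without single arrays. That held for 11 arrays each for SESN2, CDKN1A and CDT1, 13 each for PLK2 and POLA2 and 16 for CDC6, at limma adjusted p up to 0.0607, 0.0681, 0.0696, 0.0946, 0.0795 and 0.0958. Quantile normalization ended the calls of PLK2 (limma adjusted p = 0.0676) and CDC6 (0.0516). Other probe sets gave 0.097 for CDT1, 0.255 for CDC6 (limma adjusted p = 0.0983) and -0.032 and 0.007 for POLA2, none past the threshold. Without T-ALL1, whose control arrays had the high actin differences, the DNA replication mean was -0.038 (camera adjusted p = 0.103) and that of the stress response 0.058 (0.103). In CEM, DND41 and HPB-ALL alone, which seem to form the other processing run, these means were -0.023 and -0.019 (0.69 each), against 0.101 and 0.255 in T-ALL1 and KOPT-K alone. The stress response mean was 0.041 without KOPT-K (camera adjusted p = 0.0247) and 0.147 without DND41. The DNA replication mean was 0.043, 0.054 and 0.048 without CEM, KOPT-K and DND41, and 0.048 with the actin covariate. Without KOPT-K the p53 mean was 0.008 (0.418), while it was 0.062 without T-ALL1 and 0.071 with the actin covariate. The p53 call was also lost in T-ALL1 and KOPT-K alone (mean 0.065, camera adjusted p = 0.0713), in the other 3 lines alone (0.024, 0.271) and without the HPB-ALL line (mean 0.04), T-ALL1 control 2 (camera adjusted p = 0.145) or CEM control 1 (0.0652), and the DNA replication call without T-ALL1 control 2 (0.0767), T-ALL1 NBD 2 (0.0558) or KOPT-K control 2 (0.0794), or after median centring (0.0547).

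The other lists did not pass camera. Of the mitosis genes 0 of 33 rose or fell, also adjusted over the list alone (mean 0.019, camera adjusted p = 0.0964), with MKI67 at 0.16 ± 0.13 and TOP2A at 0.13 ± 0.05. The call was made without the T-ALL1, DND41 or HPB-ALL line (means 0.026, 0.042 and 0.047) and without KOPT-K NBD 1 (adjusted p = 0.049). It was also made in T-ALL1 and KOPT-K alone (mean 0.064, camera adjusted p = 0.00697) and with the mean of all probe sets per gene (0.032, 0.0265). It was not made without CEM or KOPT-K (means -0.009 and -0.01) or in CEM, DND41 and HPB-ALL alone (-0.011), where the mean was below 0. With an estimated correlation it was made without HPB-ALL (camera adjusted p = 0.0389), but not without T-ALL1 (0.163) or DND41 (0.0534) or in T-ALL1 and KOPT-K alone (0.0727). TOP2A was called without T-ALL1 control 2 (0.167, limma adjusted p = 0.0101) and by another probe set (0.232, 0.0439). Of the apoptosis regulators 1 of 30 rose, PMAIP1 at 0.23 ± 0.03, and 1 fell, BID at -0.26 ± 0.05 (1 and 2 adjusted over the list alone; mean -0.02, camera adjusted p = 0.999). Other probe sets gave 0.132 for PMAIP1 (limma adjusted p = 0.189) and -0.135 (0.0318) and -0.209 (0.0558) for BID. Of 19 endoplasmic reticulum chaperone genes HERPUD1 rose, at 0.11 ± 0.03 (1 higher and 1 lower adjusted over the list alone; mean -0.007 with camera pointing up; adjusted p = 0.995). With the preset correlation only, this list was called in opposite directions in the 2 sets of lines, higher in T-ALL1 and KOPT-K (0.106, camera adjusted p = 0.000991) and lower in CEM, DND41 and HPB-ALL (-0.081, 0.00454). With an estimated correlation neither passed (camera adjusted p = 0.0727 and 0.274). The HERPUD1 call was lost without any 1 of 16 arrays (0.096 to 0.123, limma adjusted p up to 0.0987), and another probe set gave 0.005. Of 15 heat shock genes 0 passed, also adjusted over the list alone (mean -0.019, camera adjusted p = 0.995), with HSPB1 at -0.14 ± 0.05 and HSPA4L at -0.09 ± 0.09. HSPB1 was called without DND41 NBD 1 (-0.165, limma adjusted p = 0.0475). Of 32 interferon-stimulated genes 0 rose and 4 fell, IFI35, IFITM2, IFITM1 and ISG20 at -0.29, -0.21, -0.15 and -0.13 (1 and 5 adjusted over the list alone; mean -0.002 with camera pointing up; adjusted p = 0.995). The calls of IFITM2, IFITM1 and ISG20 were lost without any 1 of 14, 7 and 15 arrays (limma adjusted p up to 0.0812, 0.0668 and 0.0979), and another probe set of ISG20 gave -0.052. Quantile normalization ended the ISG20 call (0.0597). Of 29 hypoxia and glycolysis genes 5 rose and 2 fell, also adjusted over the list alone (mean 0.007, median -0.04, camera adjusted p = 0.654), with SLC2A3, PFKFB3 and ALDOC at 0.45, 0.24 and 0.23 and ANKRD37 at -0.24. The ALDOC call was lost without any 1 of 9 arrays (limma adjusted p up to 0.0654) and with quantile normalization (0.0503). Another probe set of ANKRD37 gave 0.189, and those of SLC2A3 gave 0.46, which passed, and 0.195 (0.095). The list was called higher in T-ALL1 and KOPT-K alone (mean 0.071, camera adjusted p = 0.0244; adjusted p = 0.234 with an estimated correlation). For markers of other cell types 0 members passed, also adjusted over each list alone: 7 B cell genes (mean -0.07, camera adjusted p = 0.54; CD79A -0.23, CD79B -0.11), 3 myeloid genes (0.006, 0.683; CST3 -0.07, CSF1R 0.07) and 7 fibroblast and epithelial genes (0.024, 0.548; TAGLN 0.12, KRT18 0.12). CD79A was called without T-ALL1 control 1 (-0.301, limma adjusted p = 0.02) and by another probe set (-0.291, 0.0351). With the actin covariate the B cell list shifted by -0.141 (camera adjusted p = 0.0312).

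Of the 20 lists, 10 passed with the preset correlation and 7 with an estimated one, at camera adjusted p-values of 0.00218 for cholesterol synthesis, 0.00917 for both the Notch and the NRF2 and metallothionein lists, 0.0106 for T lineage, 0.0224 for immediate-early, 0.0315 for MYC and ribosome biogenesis and 0.0417 for NF-kB targets. Leaving out 1 line ended some of these calls with an estimated correlation. NF-kB targets missed the threshold without T-ALL1 (camera adjusted p = 0.0704), CEM (0.0809), KOPT-K (0.0504) or HPB-ALL (0.0827). Immediate-early genes missed it without CEM (0.0793) or KOPT-K (0.0867), MYC and ribosome biogenesis without KOPT-K (0.123) or DND41 (0.16), and T lineage without KOPT-K (0.0504). In T-ALL1 and KOPT-K alone 0 lists passed this way and in the other 3 lines 1, against 11 and 8 with the preset correlation. Passing with the preset correlation alone is weak evidence, since a median of 4 lists passed that way when the arrays were regrouped within lines.

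**Figure D4:**
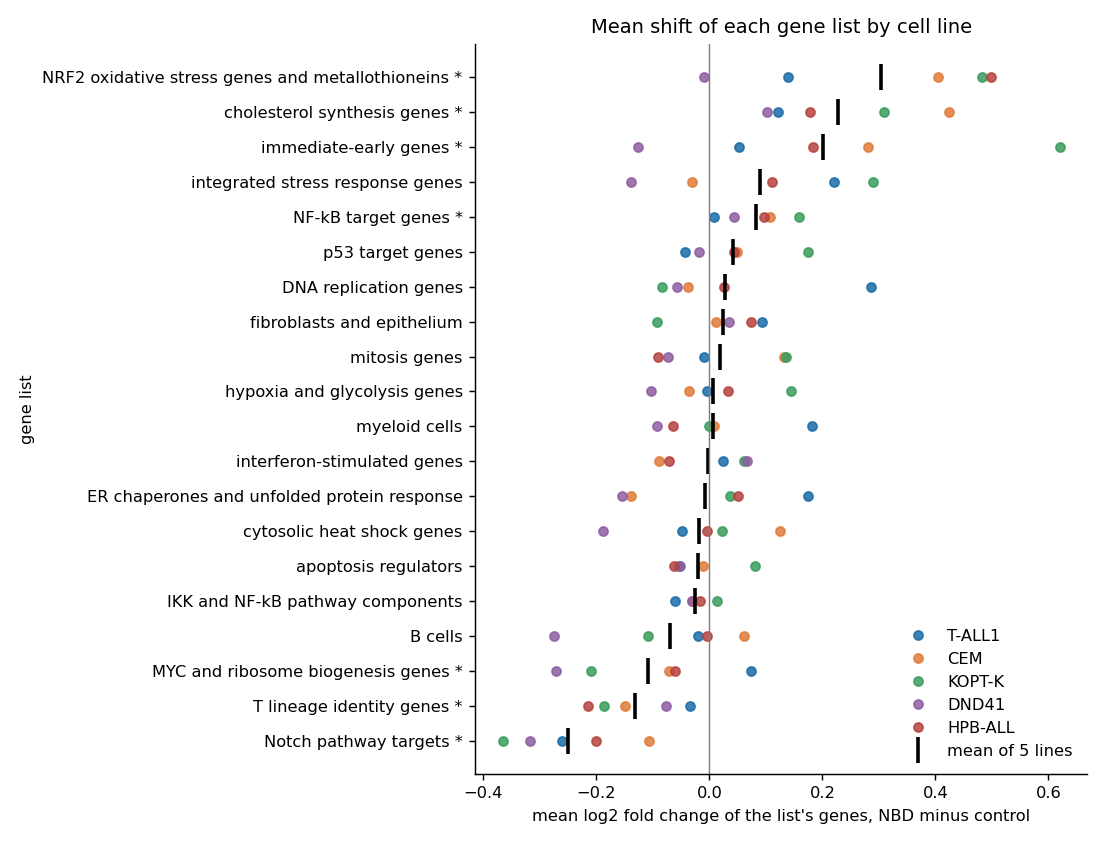
Mean log2 fold change, NBD minus control, of the genes of each list, with 1 point per line and a bar for the mean of 5 lines; an asterisk marks the 7 lists past the threshold with an estimated correlation, and B cells, myeloid cells, and fibroblasts and epithelium are markers of other cell types. The means run from -0.25 for Notch pathway targets to 0.303 for NRF2 targets with metallothioneins.

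In T-ALL1, TFAP2C rose by 1.37 ± 0.30 (SE, n = 2 per peptide; limma adjusted p = 0.0269), JUN by 1.11 ± 0.09 and ORC1, a subunit of the replication origin complex, by 1.04 ± 0.23 (0.0315). In this and each other line, the SE and p rest on the spread shared over the 10 groups, not on the line's own arrays. Across genes the log2 difference between the T-ALL1 control arrays had an SD of 0.318, against 0.154 to 0.209 in the other groups. The shared spread may therefore overstate the precision in this line. ID3 fell by 2.86 ± 0.11, HES1 fell by 2.10 ± 0.22 and LINC00597 fell by 1.96 ± 0.32 (limma adjusted p = 1.07e-08, 0.000509 and 0.00811). TFAP2C stood at 4.67 and 3.28 on the control arrays and at 5.18 and 5.51 with NBD. Its change was 2.067 without control 1 and 0.678 without control 2. The TFAP2C call was lost without NBD 1 (limma adjusted p = 0.133) or NBD 2 (0.115), and another probe set gave 0.484 (0.308). The ORC1 change was 0.573 without control 1 (limma adjusted p = 0.176), and its call was also lost without NBD 1 (0.144) or NBD 2 (0.126). LINC00597 lost its call without control 1 (-1.64, 0.0624) or NBD 1 (-1.709, 0.115). Other probe sets of HES1 gave -1.691, which passed, and 0.009. DNA replication genes rose, 14 of 34 with 0 lower (24 and 0 adjusted over the list alone; mean 0.286, camera adjusted p = 2.13e-17; adjusted p = 0.00313 with an estimated correlation). The control arrays of this line held the actin differences of 3.16 and 2.05. In all 158 genes rose and 317 fell with limma, against 97 and 78 without control 1, 1195 and 1921 without control 2, 17 and 23 without NBD 1 and 56 and 177 without NBD 2. Without an array of CEM (NBD), DND41 (control) or HPB-ALL 91 to 97 rose, and without one of HPB-ALL 208 or 209 fell. The line's own arrays alone gave 0 and 0, array weights 2 and 11 and the actin covariate 30 and 19.

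In CEM, RNA45SN5, a ribosomal RNA precursor, rose by 1.46 ± 0.14 and the metallothioneins MT1G and MT1F by 1.43 ± 0.11 and 1.37 ± 0.10 (limma adjusted p = 0.000118, 2.08e-05 and 5.74e-06). ID1 fell by 2.65 ± 0.15, ID3 by 2.31 ± 0.11 and ABCG1, a sterol exporter, by 1.47 ± 0.18 (limma adjusted p = 1.11e-06, 1.74e-07 and 0.00074). Other probe sets gave 0.334 for MT1G and -0.189, -0.36 and -0.25 for ABCG1, none past the threshold. Cholesterol synthesis genes rose, 13 of 21 with 0 lower (15 and 1 adjusted over the list alone; mean 0.425, camera adjusted p = 5.68e-21; adjusted p = 0.00388 with an estimated correlation). Mitosis, immediate-early and NRF2 and metallothionein genes also passed with an estimated correlation, at means of 0.132, 0.281 and 0.404. In all 54 genes rose and 102 fell with limma, against 89 higher without control 1, 24 and 16 without control 2, 21 and 21 without NBD 1, 24 and 20 without NBD 2, and 86 and 207 without either T-ALL1 control, which enters only the shared spread. The line's own arrays alone gave 4 and 2.

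In KOPT-K, JUN rose by 3.35 ± 0.09 (10.2-fold, n = 2 per peptide; limma adjusted p = 9.38e-11), ULBP2, a ligand of the NKG2D receptor, by 2.32 ± 0.28 (0.000619) and FOS, the partner of JUN in AP-1, by 1.98 ± 0.24 (0.000505). ID1 fell by 1.94 ± 0.15, ID3 by 1.41 ± 0.11 and HES1 by 1.21 ± 0.22 (limma adjusted p = 1.06e-05, 1.06e-05 and 0.0168). The HES1 call was lost without control 1 (-1.265, limma adjusted p = 0.106), control 2 (-1.151, 0.0739) or NBD 2 (-0.854, 0.182). Its other probe sets gave -0.771 (0.0242) and -0.113 (0.851). Immediate-early genes rose, 10 of 27 with 0 lower (16 and 0 adjusted over the list alone; mean 0.62, camera adjusted p = 5.69e-20; adjusted p = 0.00744 with an estimated correlation). Notch targets fell, 6 of 21 with 0 higher (8 lower and 1 higher adjusted over the list alone; mean -0.365; adjusted p = 0.0104 with an estimated correlation). The p53, mitosis, cholesterol and NRF2 and metallothionein lists also passed with an estimated correlation, at means of 0.174, 0.136, 0.309 and 0.483. So did MYC and ribosome biogenesis at -0.21 and T lineage at -0.186. In all 123 genes rose and 53 fell with limma, against 46 and 21 without control 1, 43 and 27 without NBD 1, 54 and 27 without NBD 2, and 186 and 107 without either T-ALL1 control. The line's own arrays alone gave 17 and 2.

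In DND41, DUSP16 rose by 1.17 ± 0.14, ASRGL1, an asparaginase, by 1.02 ± 0.21 and PIK3IP1, an inhibitor of PI3 kinase, by 0.93 ± 0.10 (SE, n = 2 per peptide; limma adjusted p = 0.000829, 0.0208 and 0.000445). EGR1, an immediate-early transcription factor, fell by 1.95 ± 0.18, CD300A fell by 1.93 ± 0.12 and CXXC5 fell by 1.51 ± 0.08 (limma adjusted p = 0.00013, 3.49e-06 and 5.6e-07). ASRGL1 lost its call without control 1 (0.687, limma adjusted p = 0.232) or NBD 1 (0.681, 0.115). Other probe sets gave 0.132, 0.24 and -0.102 for DUSP16, 0.343 for ASRGL1 and 0.701 and 0.316 for PIK3IP1, none past the threshold. Those of CD300A gave -1.697, which passed, and 0.408, which did not. MYC and ribosome biogenesis genes fell, 5 of 27 with 0 higher (12 and 0 adjusted over the list alone; mean -0.272; camera adjusted p = 0.00989 with an estimated correlation). Notch targets fell, 5 of 21 (8 adjusted over the list alone; mean -0.317; adjusted p = 0.0164), and so did heat shock genes, 3 of 15 (5 adjusted over the list alone; mean -0.188; adjusted p = 0.0415). In all 101 genes rose and 240 fell with limma, against 13 and 35 without control 1, 23 and 71 without control 2, 20 and 40 without NBD 2, and 181 and 429 without either T-ALL1 control. The line's own arrays alone gave 0 and 3.

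In HPB-ALL, the metallothioneins MT1X, MT1F and MT2A rose by 1.92 ± 0.14, 1.72 ± 0.10 and 1.58 ± 0.09 (SE, n = 2 per peptide; limma adjusted p = 7.67e-06, 1.23e-06 and 1.33e-06). CD300A fell by 1.54 ± 0.12, LZTFL1 by 1.46 ± 0.15 and DOCK1, an activator of the GTPase RAC, by 1.41 ± 0.18 (limma adjusted p = 1.94e-05, 0.000273 and 0.00212). Other probe sets gave 0.575 for MT1F, -0.956 and -0.143 for CD300A and -0.12, -0.354, 0.014 and 0.123 for DOCK1, none past the threshold. Those of LZTFL1 gave -1.362, which passed, and -0.269 and -0.046, which did not. The combined NRF2 and metallothionein list rose, 6 of 21 members with 0 lower (10 and 0 adjusted over the list alone, mean 0.499, camera adjusted p = 0.00499 with an estimated correlation). Cholesterol synthesis genes rose, 2 of 21 (4 adjusted over the list alone; mean 0.178; adjusted p = 0.0128). T lineage genes fell, 4 of 32 (6 adjusted over the list alone; mean -0.214; adjusted p = 0.0135). In all 19 genes rose and 89 fell with limma, against 9 and 25 without control 1, 8 and 20 without control 2, 9 and 19 without NBD 1, 11 and 42 without NBD 2, 34 and 174 without either T-ALL1 control, and 58 lower without either CEM NBD array. The line's own arrays alone gave 6 and 3, and array weights 117 and 484.

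Whether the lines differed in their response was tested directly. The effect on JUN had the lowest p for a difference between lines, running from 0.58 in HPB-ALL to 3.35 in KOPT-K (SE 0.09 in each line; limma moderated F-test, adjusted p = 4.92e-07), and that on ID3 from -2.86 in T-ALL1 to -0.06 in HPB-ALL (3.62e-06). RAG1, a recombinase of antigen receptor genes, was 0.61 ± 0.08 in DND41, -0.82 in KOPT-K and -0.94 in HPB-ALL (7.24e-05). CXXC5 was -1.51 in DND41 and 0.01 in KOPT-K (8.7e-05), and MT1F was 0.17 in T-ALL1 and 1.72 in HPB-ALL (8.7e-05). With other probe sets the difference missed the threshold for RAG1 (limma adjusted p = 0.851), MT1F (0.0605) and 1 of 2 of CXXC5 (0.0512), and passed for all 3 of JUN. In all 252 genes differed between lines, 119 of them among the 1156 called on average. Without 1 array the count was 106 (DND41 control 1), 125 (T-ALL1 NBD 1), 130 (CEM NBD 1), 132 (DND41 control 2), 138 (T-ALL1 NBD 2), 140 (HPB-ALL NBD 2), 142 (KOPT-K NBD 1), 143 (HPB-ALL NBD 1), 149 (CEM NBD 2), 151 (CEM control 2 and HPB-ALL control 2), 164 (DND41 NBD 2) and 1625 (T-ALL1 control 2). Some lists passed camera in opposite directions in different lines with the preset correlation. The means were 0.286 in T-ALL1 and -0.083 in KOPT-K for DNA replication, and 0.074 in T-ALL1 and -0.272 in DND41 for MYC and ribosome biogenesis. They were 0.289 in KOPT-K and -0.138 in DND41 for the stress response, and 0.136 in KOPT-K and -0.091 in HPB-ALL for mitosis. For chaperones they were 0.175 in T-ALL1 and -0.155 in DND41, for heat shock 0.125 in CEM and -0.188 in DND41, and for hypoxia 0.145 in KOPT-K and -0.104 in DND41. With an estimated correlation no list passed in both directions.

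Across genes, the effects of a pair of lines correlated at r = -0.078 (T-ALL1 and DND41) to 0.337 (CEM and HPB-ALL), with a mean of 0.14 ± 0.122 (SD over 10 pairs), and genes are not independent replicates. Over the genes in the upper part by mean level the average was 0.263. Of the genes called, 49 were higher in 2 or more lines and 96 lower. Summed over the 10 pairs, which counts a gene once for each pair, 95 calls were higher in both lines, 156 lower in both and 38 opposite. Independent calls would give 5.57, 16.78 and 20.06. Each line had its own control arrays, but the lines share 1 spread per gene, so a gene with a small spread can pass in several lines, which the independent values leave out. T-ALL1 and DND41 held 15 of the opposite calls. JUN was called higher in 5 lines, and JUND, MT1HL1 and MT2A in 4. CD300A, CD3D, GPX1, ID1, ID3, LZTFL1, NOTCH3 and SELENOH were called lower in 4. Of these, GPX1 and SELENOH, which encode selenoproteins, were singled out after their values were seen. Opposite calls in different lines were made for 33 genes, EGR1 among them, which fell in DND41 and rose in CEM and HPB-ALL by 1.30 ± 0.18 and 1.01 ± 0.18.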

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

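The tests of the T-ALL1 arrays, of list differences without T-ALL1, of the NF-kB list without KOPT-K and by processing run, of the metallothioneins and of the splits for lists with an estimated correlation were chosen after the results were seen.

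Genes and lists are given here where the NBD effect differed between lines by limma's moderated F-test or the test of a list's mean, and probe sets where a change appeared outside the gene-level tests. The effect differed for 252 genes, 33 of the 91 named ones among them. For metallothioneins the adjusted p was 0.00102 for MT1X, 0.00391 for MT1H, 0.00102 for MT1G, 5e-04 for MT2A, 8.7e-05 for MT1F, 0.00132 for MT1HL1 and 0.000374 for MT1E. For transcription factors and their inhibitors it was 4.92e-07 for JUN, 0.00301 for ATF3, 0.0201 for FOS, 8.7e-05 for EGR1, 3.62e-06 for ID3, 0.000527 for ID1 and 8.7e-05 for CXXC5. For lymphocyte genes it was 0.000848 for CD300A, 7.24e-05 for RAG1, 0.0045 for CR2 and 0.0368 for CD7. For stress and signalling genes it was 0.0137 for TNFAIP3, 0.038 for PMAIP1, 8.7e-05 for GADD45A, 0.0479 for CDKN1A, 0.0179 for ULBP2, 0.0105 for PIK3IP1 and 0.0387 for DOCK1. For metabolic and other genes it was 0.0258 for MSMO1, 0.02 for HMGCS1, 0.0111 for ABCG1, 0.000527 for SLC2A3, 0.00289 for RRS1, 0.0102 for RNA45SN5, 0.00748 for TMC6 and 0.042 for LINC00597.

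The mean shift differed between lines for 12 of the 20 lists, and for 16 without T-ALL1. The adjusted p was 0.0152 for Notch targets, 0.0152 for p53 targets, 0.000247 for mitosis, 1.52e-05 for DNA replication, 7.57e-05 for MYC and ribosome biogenesis and 0.000247 for the integrated stress response. It was 0.000118 for endoplasmic reticulum chaperones, 0.00315 for heat shock, 1.89e-05 for immediate-early genes, 0.000247 for cholesterol synthesis, 5.98e-07 for NRF2 and metallothionein genes and 0.00434 for hypoxia. For NF-kB targets it was 0.142, which missed the threshold. Without T-ALL1 these 12 passed again, and 4 more did: apoptosis regulators (0.0122), interferon-stimulated genes (0.0184), B cell markers (0.0168) and fibroblast and epithelial markers (0.0371). Of 6060 probe sets with several genes or none and a level above the filter, 48 were higher and 79 lower with NBD on average by limma, with changes of -0.56 to 0.91, and no explanation was tested for them.

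The first pattern weighed is the 475 genes called in T-ALL1, whose control arrays had the highest actin 3' to 5' differences. Without control replicate 1 the fit called 175 genes (97 higher, 78 lower), 111 of the 475 among them and all 111 in the same direction, which argues against that array as the whole cause. These calls are no independent check, since both fits share control replicate 2 and the NBD arrays, and leaving an array out also alters the shared spread. Without control replicate 1 the changes of the 475 genes had a median ratio of 0.856 to those with it (quartiles 0.745 and 0.994). That this array added to the count is not excluded, since far more genes were called without control replicate 2. With the actin difference as a covariate the median ratio was 0.601 (quartiles 0.287 and 0.931), between the bounds set for and against, and 12 of the 475 were still called, as the median absolute change went from 0.502 to 0.309 and the median SE from 0.102 to 0.186. RNA integrity and the peptide therefore cannot be told apart for these genes, since the actin difference separates the peptides in that line, and an effect of NBD stays open beside it.

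The second pattern is the rise of NF-kB targets under a peptide that blocks NF-kB. Members shared with the immediate-early list are not its whole cause, since without those 3 the camera p was 0.000178 (0.0124 with an estimated correlation) and the mean 0.075 against 0.083. Whether KOPT-K alone or 1 processing run alone gave the rise stays open. Without KOPT-K the mean was 0.064 (camera adjusted p = 0.00152 with the preset correlation, 0.0504 with an estimated one), and the runs gave 0.084 and 0.082 (0.00697 and 0.000786 preset, 0.234 and 0.107 estimated). By line the mean was 0.009 in T-ALL1, 0.158 in KOPT-K, 0.107 in CEM, 0.044 in DND41 and 0.096 in HPB-ALL. The mean of the run of T-ALL1 and KOPT-K thus came almost wholly from KOPT-K. A response to the peptide that differs from loss of NF-kB activity stays open and was not tested, as no array measures NF-kB activity.

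The third pattern is the rise of metallothionein genes. Near-identical family members share probes, and of 14 metallothionein probe sets, 10 rose and 4 had names without the suffix for shared probes. Of those 4, 0 were at least 1 log2 unit above the filter, a requirement added after their levels were seen, and 0 such probe sets rose, so which family members rose cannot be told apart. SLC30A1, a zinc exporter with its own probe set, rose by 0.204, which is consistent with metal-responsive transcription as a hypothesis found and tested on the same data.

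Whether chance could give these counts was assessed with 100 splits of the arrays within lines, the real one included. If the arrays of a group share a culture, such splits exclude chance between arrays only and leave chance between cultures open. In the average effect the real split called 1156 genes and the highest other 6, so 1 of 100 splits gave as many. Chance between arrays, with no NBD effect on any gene, is therefore an unlikely source of that count as a whole. Splits that mix the peptides leave any NBD effect in the spread, which can lower their counts. The gap from 1156 to 6 thus does not tell how many calls are real. With the preset correlation the real split passed 10 lists and the highest other 12, and 7 of 100 gave as many. Chance between arrays is therefore not excluded for that count of lists. The other splits passed a median of 4 lists this way, so passing with the preset correlation is weak evidence for any 1 list. With an estimated correlation the real split passed 7 lists and the highest other 4, 1 of 100 giving as many. That count was added after the results were seen. Splits that mix the peptides also leave any NBD effect in the spread from which the correlation is estimated, which can lower their counts. Chance between arrays is therefore not taken as excluded for that count. With lines as replicates the real split and the highest other each called 0 genes, 16 of 16 splits gave as many, and 16 splits are too few for a share under 0.05.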

How the results depend on the processing

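The fits by processing run, the actin covariate and an estimated correlation for subsets of lines were chosen after seeing the data. The cause of a change was not tested unless a setting's own construction gives it. Quantile normalization kept all 14 counts within 1.5 times and ended 4 calls among 109 changes of named genes, those of PLK2, CDC6, ISG20 and ALDOC. In addition fry kept all 20 list calls. Leaving out single arrays gave 2180 gene comparisons (2016 same, 161 weaker, 3 stronger). No sign turned where either fit made a call, and signs were not compared where neither did. Signal near the filter limits dim genes, whose removal or return moved the counts below.

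Counts are given as higher and lower. Each line's arrays alone, with far fewer degrees of freedom, gave T-ALL1 0 and 0, CEM 4 and 2, KOPT-K 17 and 2, DND41 0 and 3, HPB-ALL 6 and 3. Without the filter T-ALL1 had 77 and 186, DND41 54 and 148, HPB-ALL 12 and 56, and 158 genes differed between lines; with a stricter one KOPT-K had 83 lower, HPB-ALL 146 lower, and 426 differed. The mean of all probe sets gave T-ALL1 320 higher, HPB-ALL 12 and 48, and a mitosis shift of 0.032, then called (camera adjusted p = 0.0265). Without probe sets marked as shared, T-ALL1 had 104 higher, CEM 21 higher, KOPT-K 61 and 20, DND41 53 and 119, HPB-ALL 4 and 39, the average 185 higher, and 146 differed. Median centring gave T-ALL1 102 higher and a DNA replication shift of 0.014. The trended robust prior gave T-ALL1 272 and 520, CEM 87 higher, KOPT-K 91 lower, DND41 174 and 406, lines as replicates 69, and 596 differing. Array weights gave T-ALL1 2 and 11, CEM 93 and 222, DND41 209 and 445, HPB-ALL 117 and 484. The additive model gave 184 higher on average. The mean r between lines was 0.263 over the upper part of genes by level.

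The replicate number as a block gave T-ALL1 20 and 56, CEM 18 and 12, KOPT-K 37 and 14, DND41 10 and 34, HPB-ALL 8 and 14, the average 127 and 324, and 37 differing. It changed no list call and ended 22 calls among the 109 changes of named genes, those of RELB (limma adjusted p = 0.0518), SLC3A2 (0.0705), CD1E (0.0829), ANKRD37 (0.0832) and DTL (0.113) among them. Same-numbered arrays deviated with correlations of -0.281, -0.045, -0.181, 0.143 and -0.096, and 1 of 5 is over 0.1, so the numbers were not taken to pair the arrays.

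Without CEM the average was 192 and 465, without KOPT-K 147 higher, without HPB-ALL 170 and 414. Without T-ALL1 the shifts were 0.026 for mitosis (then called), 0.058 for the stress response (call lost) and -0.038 for DNA replication. Mitosis was called without DND41 (0.042) and HPB-ALL (0.047); p53 lost its call without KOPT-K (0.008) and HPB-ALL (0.04). Calls in subsets of lines use the preset correlation. T-ALL1 and KOPT-K alone gave an average of 16 and 8, with p53 0.065 and MYC -0.068 lost and mitosis 0.064, chaperones 0.106 and hypoxia 0.071 called. The other run gave p53 0.024 (lost), DNA replication -0.023, stress response -0.019 (both calls lost) and chaperones -0.081, called lower (camera adjusted p = 0.00454) against the call of higher in the first run (0.000991), both with the preset correlation only (0.274 and 0.0727 with an estimated one). The actin covariate gave T-ALL1 30 and 19, CEM 224 lower, KOPT-K 203 and 82, DND41 207 and 361, HPB-ALL 35 and 152, the average 497 lower, and a B cell shift of -0.141. With an estimated correlation the adjusted p was 0.103 for p53, 0.172 for DNA replication and 0.179 for the stress response.

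Leaving out 1 array gave, higher then lower, 193 to 702 and 561 to 1612 on average; T-ALL1 17 to 1195 and 23 to 1921; CEM 21 to 89 and 16 to 207; KOPT-K 43 to 186 and 21 to 107; DND41 13 to 181 and 35 to 429; HPB-ALL 8 to 34 and 19 to 174; and 106 to 1625 differing. T-ALL1 control 2 gave the highest value on average, in T-ALL1 and for the difference. List shifts ran from 0.03 to 0.051 for p53, 0.018 to 0.036 for DNA replication and 0.013 to 0.025 for mitosis.

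Of 62 called results of named genes with other probe sets (differences between lines included), all of these were called the same way for 21, some for 16 and none for 25. Other probe sets turned the sign, none past the threshold, for NOTCH3 (0.032), WDR4 (0.006), ANKRD37 (0.189), ATF3 (-0.046), POLA2 (0.007), NOP16 (0.081 and 0.07), HES1 in T-ALL1 (0.009), CD300A (0.408) and DUSP16 (-0.102) in DND41, and DOCK1 in HPB-ALL (0.014 and 0.123). With lines as replicates all 65 average calls among 79 named genes compared were lost.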

Other observations

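The test of selenoprotein genes was chosen after the values of GPX1, SELENOH, SELENOW, GPX4 and SELENOK had been seen. Its prediction was written before those of the other members were looked at as a class, although TXNRD1 among them also belongs to the NRF2 and metallothionein list.

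Genes outside the lists moved in several lines, and those named here were chosen after their values were seen. TFRC, the transferrin receptor through which cells take up iron, rose by 0.35 ± 0.04 on average (SE, 2 arrays per group; limma adjusted p = 8.16e-05) and was called higher in 3 lines. GPX1, a glutathione peroxidase, fell by 0.50 ± 0.04, SELENOH, a nucleolar selenoprotein, by 0.41 ± 0.03 and SELENOW by 0.30 ± 0.03 (limma adjusted p = 1.96e-05, 1.51e-06 and 4.39e-05), GPX1 and SELENOH being called lower in 4 lines. GPX4, which reduces lipid peroxides, fell by 0.14 ± 0.04 (0.0345), while SELENOK was 0.04 ± 0.03 (0.554).

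Lower transcripts of selenoprotein genes as a class might have accounted for this. The 14 other selenoprotein genes kept by the filter, of 19 in all, were tested without the 5 already seen. Their mean change was -0.01, 0 of them rose or fell by limma (0.209 was the lowest adjusted p, for TXNRD1), and camera gave p = 0.723 (0.714 with an estimated correlation). The hypothesis of a change of the whole class was therefore not borne out. A change confined to some members is not covered by this test, since the members that fell were left out of it. Why GPX1, SELENOH and SELENOW fell stays open.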
